A study of Mus musculus with 36 samples.

How the data were processed

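Bulk RNA sequencing of mouse muscle satellite cells was analysed in 36 libraries, each from a separate sample by the labels. The labels describe cells sorted from hindlimb muscle of C57BL/6 mice, as YFP-positive cells in QSC and at 1 DPI and as a CD34-YFP+ fraction at 3 DPI, after tamoxifen in Pax7-CreER;ROSA26YFP mice with or without conditional Drp1 alleles. It is not stated in the labels how the wild-type cells of the young and old mice, which carry no stated reporter, were sorted. Cd34 belongs to a gate and is not read as a finding. Injury was by cardiotoxin. Per the labels, RNA was extracted with a PicoPure kit and sequenced single-end on an Illumina HiSeq; both a low-input kit and a standard directional protocol are named, so the library type of each sample is open.

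The authors' processing notes name CASAVA 1.8.2, cutadapt 1.7.1, RSEM 1.3.1 and the build GRCm38; the aligner is not given in the sources used here. The deposited values are TPM in both tables, as the names of the files in the labels state, and the libraries of both tables have the same sum. The gene identifiers were read as Ensembl annotation of GRCm38, and symbols, types and positions came from GENCODE M21: 55144 of 55471 identifiers had a symbol there and 327 had none. Tested on the values, every library of the Drp1 table lay on whole multiples of its own smallest step (100% within a tolerance of 0.001 step), so TPM rounded to 2 decimals had been rescaled per library. The young and old table held no 0. Of its genes, 42208 had a lowest value shared by libraries, moved by more than 0.01 log2 from the commonest lowest value for 42.2% of them, and 98.2% of low values of 17601 genes were whole multiples of it or lay midway between them. A small constant and a factor per gene, shared by all 15 libraries, had therefore been applied before the columns were scaled, and no label says why. The factor cancels in fold changes without a pseudocount, but not in levels, in the filter or in fold changes with a pseudocount. The tables were never combined in a fit. No 2 libraries were identical, and the smallest median log2 difference between libraries was 0.263. TPM keep no depth, so depth and counting error are unknown.

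Groups were taken from the labels before the data were examined, as were the comparisons, tests, gene lists, alternatives and the rule for named genes. Values were taken as log2(TPM + 1). Genes with at least 1 TPM in at least 3 libraries of a table were kept, 18343 in the Drp1 table and 16949 in the other. Each table was fitted with limma 3.58.1 in R 4.3.3 with a mean per group and a trended prior variance. Contrasts were tested two-sided with Benjamini-Hochberg adjusted p over all genes of a comparison at a threshold of 0.05. They were KO against control in each state, old against young in QSC and at 1 DPI, each injury step within a genotype or age, and the interactions. Young and old cells were not compared at 3 DPI, because that table has no young group of that day. Fold changes are given as log2 of TPM + 1, so those of genes near 0 TPM depend on the pseudocount. Files were read and other tests run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

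There were 38 gene lists of 935 entries, of which 10 hold markers of other cell types. A list needed 5 measured members, which left 37 in the Drp1 table and 36 in the other. Lists were tested with limma camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. With the preset value 11, 4 and 2 lists passed between genotypes in QSC, at 1 DPI and at 3 DPI, and 14 and 15 between ages in QSC and at 1 DPI. With an estimated correlation 0, 0, 1, 0 and 1 passed.

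Named genes were chosen by rule. For a genotype or age comparison these were Dnm1l, up to 6 largest changes in each direction among called genes with a mean of at least 5 TPM in the higher group and no overlap between libraries, up to 4 members of smallest p from at most 5 lists past the test, and Pax7, Myod1, Myog, Mki67 and Cdkn1a. Predicted models and clone names were left out. For injury steps the rule took 3 genes in each direction and the same markers, and for interactions up to 4 of smallest p. A member of a fixed list could also be named as an example. Genes outside the rule, chosen after their values were seen, were Gm24682, Gm5874, Gm14893, Gm2427, Gm48294 and Gm49521. One gene that the rule reached is not reported here. Other genes that the rule reached stand in the result tables and are not all printed. Transcripts of named genes were searched against all transcripts with BLAST 2.17.0 for stretches of at least 100 bases at 95% identity, and shared sequence was named where it covers much of a transcript.

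The fit was tested on simulated data, drawn from the fitted means and spread with no group difference, to which changes were added in 200 genes. A change of 2 on the log2 scale was recovered for 82, 92, 90, 87 and 84% of genes in the 5 genotype and age comparisons, a change of 1 for 50, 37, 43, 33 and 15%, always with the right sign, and 4 to 9 unchanged genes were called.

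Alternatives set beforehand were a pseudocount of 0.1, no filter, median-of-ratios scaling, array quality weights, a fit of only the groups compared, replicate number as a block, leaving out each library in turn, and a mean of at least 5 TPM for the comparison of tables. Chosen after seeing the data were a covariate of the macrophage and neutrophil marker means, a fit without the 7 libraries of array weight below 0.6 (4 and 3 per table), no pseudocount in the young and old table, gene lists under every setting, and the choice of genes for scaling in that table. Low array weights fell on control 1 DPI library 3, KO 1 DPI library 2, KO 3 DPI libraries 2 and 3, old QSC libraries 1 and 3, and old 3 DPI library 3. The number of calls was also compared with that of other splits of the same libraries. No column of values was left out. The integrated stress response at 3 DPI and the mitosis list at 1 DPI were chosen to lead their sections after the results were seen.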

Results

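RNA was sequenced from satellite cells, the stem cells of skeletal muscle, sorted from mouse hindlimb muscle. Gene expression was measured as TPM, which give each gene its share of all transcripts in a library, for 55471 gene identifiers in 36 libraries. A table of 21 libraries held cells from mice with a conditional deletion of Drp1, here called KO, and from tamoxifen-treated controls. Drp1 is the protein of the gene Dnm1l, a dynamin-like GTPase that divides mitochondria. Control cells were taken from uninjured muscle (QSC, quiescent satellite cells, n = 3), 1 day after cardiotoxin injury (1 DPI, n = 4) and 3 days after it (3 DPI, n = 3). KO cells were taken at the same states, with n = 3, 4 and 4. A table of 15 libraries held wild-type cells of young mice, aged 3 months, and old mice, aged 24 months. Its groups were young and old QSC, young and old 1 DPI, and old 3 DPI, with n = 3 in each. The tables were fitted separately. Between 12325 and 14969 genes reached 1 TPM in a library of the first table, and between 12958 and 14636 in the other. The sequencing depth is unknown, since TPM keep no depth, so no counting interval can be given. The p-values measure the spread between these libraries, which may hold technical as well as animal differences.

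Dnm1l (ENSMUSG00000022789, GRCm38 chromosome 16, 16312230 to 16358959, minus strand) was read first in every library, because it is the deleted gene. In QSC the 3 control libraries held 38.2, 39.5 and 30.9 TPM, and the 3 KO libraries held 32.7, 34.0 and 43.4 TPM. At 1 DPI the 4 control libraries held 52.9, 48.8, 43.9 and 49.5 TPM, and the 4 KO libraries held 30.4, 38.5, 29 and 41.0 TPM. At 3 DPI the 3 control libraries held 69.8, 61.5 and 64.9 TPM, and the 4 KO libraries held 29.2, 22.2, 37.5 and 24.2 TPM. Dnm1l fell in KO cells at 3 DPI, to 28.3 ± 6.82 TPM (SD, n = 4) from 65.4 ± 4.20 TPM (n = 3), a log2 fold change of -1.21 (SE 0.18, limma adjusted p = 0.00115). At 1 DPI the difference was -0.49 (SE 0.17, limma adjusted p = 0.699), with all 4 KO libraries below all 4 controls. In QSC it was 0.02 (SE 0.19, limma adjusted p = 1.0), at 36.7 ± 5.84 TPM in KO and 36.2 ± 4.64 TPM in control cells. The gene's TPM also counts exons outside a deleted part, so these values do not by themselves check the genotype labels. Fitted on the 3 DPI groups alone, the adjusted p at 3 DPI was 0.131.

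**Figure D1:**
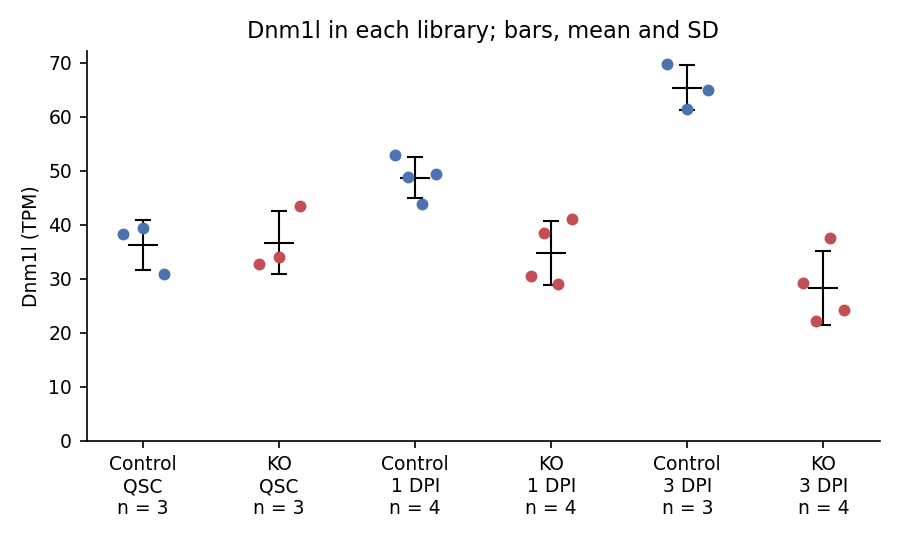
Dnm1l in TPM on the vertical axis, with 1 point per library, for control and KO cells in QSC, at 1 DPI and at 3 DPI; lines and bars are the mean and SD of each group. At 3 DPI the 4 KO libraries lie between 22.2 and 37.5 TPM, below the 3 controls at 61.5 to 69.8 TPM, while the QSC groups overlap.

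KO cells were compared with control cells at rest, where Dnm1l was not lower in KO libraries, so a loss of Drp1 is not seen in these values. Metap2, a methionine aminopeptidase, rose to 625 ± 134 TPM (SD, n = 3) in KO cells from 343 ± 44.0 TPM (n = 3), a log2 fold change of 0.85 (SE 0.16, limma adjusted p = 0.0215). Tgfbr3, a co-receptor for TGF-beta ligands, fell from 199 ± 29.8 to 54.9 ± 17.9 TPM (log2 -1.88, limma adjusted p = 0.0124). Slc38a1, a neutral amino acid transporter, fell from 140 ± 11.3 to 57.7 ± 7.81 TPM (log2 -1.27, limma adjusted p = 0.000347). Tceanc2 stood at 212 ± 87.8 TPM against 6.45 ± 0.838 TPM (log2 4.76, limma adjusted p = 0.000391), and its differences at 1 and 3 DPI were 1.19 and -0.75, neither past the test. It was as uneven in wild-type young libraries of the other table, at 1.67, 148 and 4.04 TPM in QSC and 14.4, 4.78 and 108 TPM at 1 DPI, and in KO 1 DPI libraries, at 18.7, 141, 11.3 and 102 TPM. Fance, a Fanconi anaemia gene, rose from 2.04 ± 0.605 to 6.96 ± 1.89 TPM (log2 1.38). Eno1b rose from 15.7 ± 3.59 to 86.7 ± 5.77 TPM (log2 2.41), but it shares most of its sequence with Eno1 and its reads cannot be assigned with certainty. The myogenic genes did not pass: Pax7 was at 8.66 ± 2.80 against 6.61 ± 1.40 TPM, Myod1 at 360 ± 110 against 366 ± 30.2 TPM, and Myog at 91.2 ± 76.8 against 30.2 ± 10.7 TPM. Mki67, a proliferation marker, was at 3.69 ± 4.76 against 0.497 ± 0.339 TPM, and Cdkn1a at 882 ± 82.5 against 874 ± 70.3 TPM. Of 14 alternative fits the call was lost in 7 for Fance, 6 for Metap2, 5 for Tgfbr3 and 2 for Slc38a1.

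Nuclear-encoded subunits of oxidative phosphorylation (OXPHOS), which make ATP in mitochondria, lay above 0 for 70 of 76 genes in KO QSC, with a median log2 fold change of 0.21 (limma camera adjusted p = 1.23e-13). The list had adjusted p = 0.736 with an estimated correlation, and no subunit was called over all genes tested, against 1 adjusted over the list alone. An example was Ndufs8, at 104 ± 18.6 against 71.9 ± 6.93 TPM (log2 0.52). TCA cycle genes lay above 0 for 17 of 19 (median 0.16, camera adjusted p = 0.00259, adjusted p = 0.736 with an estimated correlation), with 0 called by limma and 0 adjusted over the list alone; Idh2 stood at 0.59. Mitochondrial ribosomal proteins had 59 of 78 above 0 (median 0.19, camera adjusted p = 4.27e-06, adjusted p = 0.777 with an estimated correlation). None of these was called over all genes, and 1 was adjusted over the list alone. Mitosis genes had 24 of 29 above 0 (median 0.65, camera adjusted p = 6.26e-07, adjusted p = 0.736 with an estimated correlation), with 0 called and 0 adjusted over the list alone; Ccnb1, a mitotic cyclin, stood at 1.7. KO QSC library 3 had a mitosis mean of 2.98 log2(TPM + 1), against 0.94 to 1.69 in the other 5 libraries. Without it, the medians were 0.05 for mitosis (camera adjusted p = 0.913, on the lower side), -0.00 for mitochondrial ribosomal proteins (0.891), 0.13 for OXPHOS (0.000394) and 0.09 for the TCA cycle (0.0696).

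On the lower side in KO QSC were 8 of 11 heat shock genes, which encode protein chaperones (median -0.06, mean -0.29, camera adjusted p = 0.00259, adjusted p = 0.736 with an estimated correlation). No heat shock gene was called over all genes tested and 2 were adjusted over the list alone. Hspa8 stood at 4044 ± 698 against 6649 ± 455 TPM (log2 -0.73, limma adjusted p = 0.0758). A pseudogene with 99.7% identity to Hspa8 over its whole length was called higher in KO QSC (log2 10.11, limma adjusted p = 5.53e-09). Which copy changed is therefore uncertain. Interferon genes (21 of 29 below 0, median -0.26), immediate-early genes (17 of 21, median -0.16) and cytosolic ribosomal proteins (64 of 75, median -0.06) passed the preset test at camera adjusted p = 0.00968, with 0 members called and 0 adjusted over the list alone. Their adjusted p were 0.777, 0.736 and 0.961 with an estimated correlation. The median of immediate-early genes was 0.05 without KO QSC library 3 (camera adjusted p = 0.913), and their call was lost without control library 1 (0.273) or 3 (0.124). Without KO QSC library 2 the median of cytosolic ribosomal proteins was 0.02 (0.678), and without control library 2 it was -0.06 (0.0944). Markers of mature myofibres (14 of 19 below 0, median -0.29) and of erythroid cells (5 of 5, median -1.10) had the same preset adjusted p of 0.00968, and both had adjusted p = 0.736 with an estimated correlation. The myofibre median was -0.08 without KO QSC library 1 (camera adjusted p = 0.585) and -0.14 without control QSC library 2 (0.0944), and the erythroid call was lost without control library 1 (0.123), KO library 1 (0.0663) or KO library 2 (0.156). The heat shock median was -0.02 without KO library 3 (0.0696). The lists closest to the function of Drp1 did not pass: fission and fusion genes had a median of 0.08 (camera adjusted p = 0.209) and mitophagy genes -0.03 (adjusted p = 0.556).

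Of 18343 genes tested in QSC, 39 passed limma at an adjusted p of 0.05, 19 higher and 20 lower in KO cells, and 870 had an unadjusted p under 0.05. Of the 39, 31 were pseudogenes or predicted models and 8 were named protein-coding genes. The count was 23 when only the QSC groups were fitted, 75 with array weights, 81 with no filter on low values, and 60 without KO QSC library 1.

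At 1 DPI the comparison asked how KO and control cells differ as they leave quiescence. Cep85, which encodes a centrosomal protein, fell to 62.5 ± 22.2 TPM (SD, n = 4) in KO cells from 161 ± 37.3 TPM (n = 4), a log2 fold change of -1.39 (SE 0.23, limma adjusted p = 0.00374). Cox7a2, a subunit of cytochrome c oxidase, fell from 492 ± 65.1 to 305 ± 41.2 TPM (log2 -0.69, limma adjusted p = 0.0102). Tgfbr3 fell from 74.9 ± 2.57 to 28.8 ± 14 TPM (log2 -1.46, limma adjusted p = 0.0317), and Lbh, a transcription cofactor, from 32.7 ± 6.48 to 14.1 ± 2.65 TPM (log2 -1.16, limma adjusted p = 0.041). Both calls were lost in 13 of 16 alternative fits, that of Cox7a2 in 3 and that of Cep85 in 2. Snhg3 (log2 -0.85), Tuba1c (-0.78), the ribosomal protein gene Rps7 (-0.71) and Eno1b (2.30) also passed. These 4 share long stretches with other genes, so which copy changed is uncertain, and the calls of Tuba1c, Snhg3 and Rps7 were lost in 7, 5 and 5 of the 16 fits. Pax7 was at 15.5 ± 3.93 against 14.3 ± 4.59 TPM, Myod1 at 298 ± 84.2 against 287 ± 63.5 TPM and Myog at 18.1 ± 9.32 against 17.9 ± 11 TPM. Mki67 was at 23.3 ± 2.96 against 35.7 ± 11 TPM (log2 -0.55) and Cdkn1a at 280 ± 118 against 245 ± 39.5 TPM; none of these 5 passed.

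Mitosis genes lay below 0 in KO cells for 29 of 29 members at 1 DPI, with a median of -0.58 (camera adjusted p = 3.70e-12, adjusted p = 0.944 with an estimated correlation). No mitosis gene was called by limma and 0 were adjusted over the list alone; Kif23, a kinesin of cytokinesis, stood at 24.6 ± 9.44 against 47.6 ± 12 TPM (log2 -0.96) and Cenpa, a centromeric histone, at -0.83. S phase genes lay below 0 for 26 of 30 (median -0.14, camera adjusted p = 0.0105, adjusted p = 0.944 with an estimated correlation), with 0 called and 0 adjusted over the list alone. OXPHOS subunits lay below 0 for 70 of 76 (median -0.11, camera adjusted p = 2.36e-06, adjusted p = 0.944 with an estimated correlation), with Cox7a2 called over all genes and 1 adjusted over the list alone. Cytosolic ribosomal proteins lay below 0 for 62 of 75 (median -0.06, camera adjusted p = 0.0187, adjusted p = 0.944 with an estimated correlation), with 1 called and 2 adjusted over the list alone, in opposite directions. Without KO 1 DPI library 2 the medians were 0.00 for OXPHOS (adjusted p = 0.906), 0.04 for S phase (0.915) and 0.10 for cytosolic ribosomal proteins (2.5e-05, now on the higher side). Without control library 4 these 3 were -0.05, -0.11 and -0.00 (0.116, 0.116 and 0.905), and without control library 2 the calls of the last 2 were lost (0.206 and 0.37). KO library 2 also held the most macrophage marker RNA of the 8, with a mean of 7.98 log2(TPM + 1) against 3.59 to 6.68. Fission and fusion genes (median -0.05, camera adjusted p = 0.488) and mitophagy genes (0.13, adjusted p = 0.488) did not pass.

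At 1 DPI 51 genes passed limma, 23 higher and 28 lower, with 963 at an unadjusted p under 0.05. Of the 51, 40 were pseudogenes or predicted models and 10 were named protein-coding genes. Fitted on the 1 DPI groups alone, 33 passed.

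At 3 DPI, when control cells had switched on differentiation genes, KO cells were again compared with controls. Fgf21, a hormone induced by mitochondrial and amino acid stress, rose to 28.5 ± 6.65 TPM (SD, n = 4) from 5.94 ± 2.18 TPM (n = 3), a log2 fold change of 2.11 (SE 0.37, limma adjusted p = 0.00788). Slc7a3, a transporter of cationic amino acids, rose from 1.79 ± 1.36 to 17.9 ± 3.35 TPM (log2 2.90, limma adjusted p = 0.0352), Abl2, a tyrosine kinase, from 4.43 ± 1.01 to 12.4 ± 1.71 TPM (1.31, adjusted p = 0.00558) and Pip4p2, a phosphoinositide phosphatase, from 54.0 ± 5.54 to 127 ± 9.95 TPM (1.22, adjusted p = 0.00115). Rab35, a GTPase of endosome recycling, fell from 18.6 ± 3.94 to 4.90 ± 1.87 TPM (log2 -1.77, limma adjusted p = 0.00151), and Tgfbr3 from 10.5 ± 1.71 to 2.61 ± 1.48 TPM (-1.75, adjusted p = 0.0105). Tuba1c (-1.19), Rps7 (-0.75) and Eno1b (1.73) passed again, with the same doubt over shared sequence. Myogenic genes did not pass: Pax7 was at 6.03 ± 2.68 against 6.24 ± 0.817 TPM, Myod1 at 185 ± 30.0 against 193 ± 5.71 TPM and Myog at 782 ± 103 against 846 ± 126 TPM. Mki67 was at 26.8 ± 6.74 against 29.2 ± 5.95 TPM and Cdkn1a at 610.3 ± 28.6 against 635 ± 80.4 TPM. The call of Fgf21 was lost in 5 of 15 alternative fits: without control 3 DPI library 1 or library 2, with a pseudocount of 0.1, with only these 2 groups fitted and with the replicate number as a block. That of Slc7a3 was lost in 11, those of Eno1b and Rps7 in 9 each, that of Tgfbr3 in 5 and that of Abl2 in 4.

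Genes of the integrated stress response, targets of the transcription factor ATF4 that serve amino acid supply and stress defence, lay above 0 in KO cells at 3 DPI for 31 of 31 members. Their median was 0.35 and their mean 0.52 (limma camera adjusted p = 6.26e-14, and adjusted p = 3.69e-05 with an estimated correlation). Fgf21 was called over all genes tested, and 9 members passed when adjusted over the list alone. These included Pck2, mitochondrial phosphoenolpyruvate carboxykinase, at 30.8 ± 6.17 against 11.5 ± 1.78 TPM (log2 1.34, SE 0.34). They also included Nupr1, a stress-induced chromatin protein, at 147 ± 19.4 against 85.9 ± 11.4 TPM (0.76), and Slc3a2, an amino acid transporter subunit, at 278 ± 38.7 against 202 ± 11.8 TPM (0.45). Asns, asparagine synthetase, stood at 0.85, and Chac1, a glutathione-degrading enzyme, at 1.20. Atf4 itself stood at 0.26 and Ddit3 at 0.00. The list mean was 5.45 to 5.6 log2(TPM + 1) in the 4 KO libraries and 4.95 to 5.02 in the 3 controls. Fitted on the 3 DPI groups alone the adjusted p was 0.0115 with an estimated correlation.

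**Figure D2:**
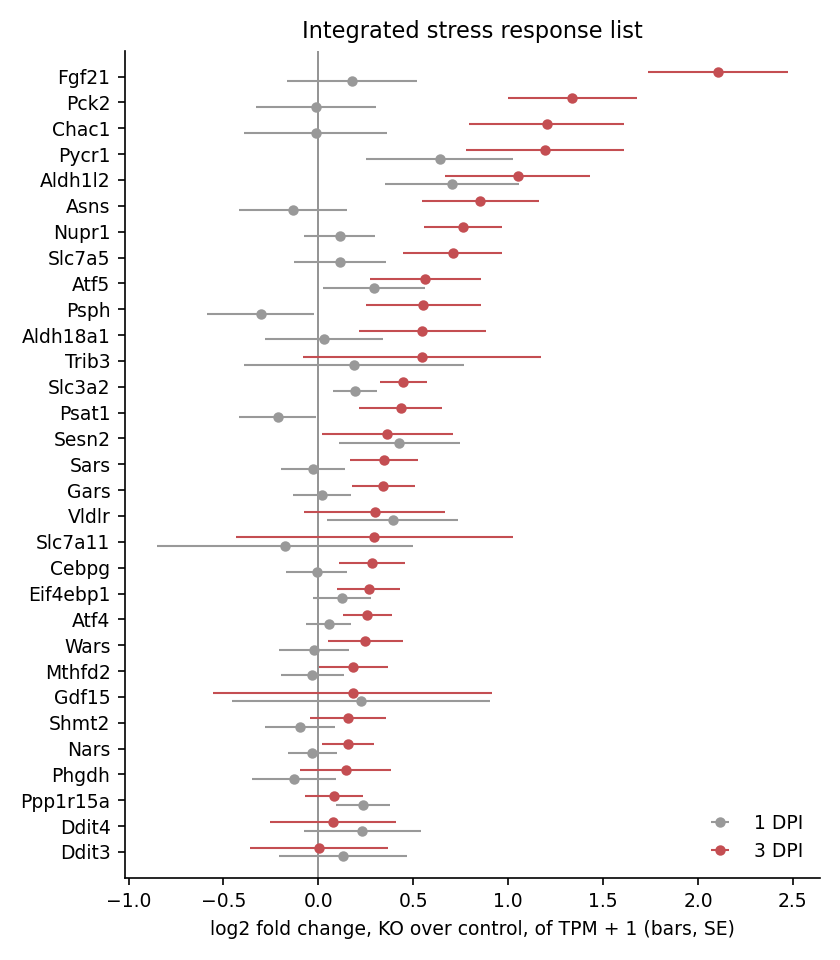
Log2 fold change of KO over control cells on the horizontal axis for each of the 31 genes of the integrated stress response list, at 1 DPI in grey and 3 DPI in red; bars are the SE. At 3 DPI all 31 points lie at or right of 0, with Fgf21 at 2.11 and Pck2 at 1.34, a direction that median-of-ratios scaling did not flip for the list.

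OXPHOS subunits lay below 0 for 72 of 76 genes in KO cells at 3 DPI (median -0.13, camera adjusted p = 6.77e-06, adjusted p = 0.997 with an estimated correlation), with 0 called by limma and 0 adjusted over the list alone. Cox7a2 was at 566 ± 68.7 against 754 ± 29.1 TPM (log2 -0.42). Fission and fusion genes had a median of -0.06 (camera adjusted p = 0.653), with Dnm1l as the 1 member called and the 1 adjusted over the list alone, and mitophagy genes of 0.07 (adjusted p = 0.598). Across all genes 52 passed limma at 3 DPI, 29 higher and 23 lower, with 996 at an unadjusted p under 0.05. Of the 52, 37 were pseudogenes or predicted models and 14 were named protein-coding genes.

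The genes called between genotypes were shared between states more often than unrelated lists would be. QSC shared 22 called genes with 1 DPI and 22 with 3 DPI, and 1 DPI shared 35 with 3 DPI, every one with the same sign, where unrelated lists would share 0.0544, 0.0551 and 0.0715. In all 3 states 22 genes were called, 18 of them pseudogenes. Tgfbr3 and Eno1b were among the 22. Of the 85 genes called in any state, 59 were pseudogenes or predicted models. The 3 comparisons share no library, and no direction of a gene list given above for them flipped under median-of-ratios scaling.

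The change of the genotype difference over time was tested as an interaction. Between QSC and 1 DPI limma called 4 genes, a small RNA and 3 pseudogenes, named here only after their values were seen. Gm24682, the small RNA, was above 0 in this table only in KO QSC, at 25.9, 10.1 and 22.7 TPM, but also stood at 7.93 TPM in a wild-type young QSC library and 24.04 TPM in a young 1 DPI library of the other, and Gm5874 was at 9.93 to 20.6 TPM in control 1 DPI and at 0 in every KO 1 DPI library. Gm14893 was above 0 in this table only in control QSC, and Gm2427 was the fourth, with its call lost in 14 of 21 alternative fits. Between 1 and 3 DPI limma called 0 genes, with 831 at an unadjusted p under 0.05. The integrated stress response list differed between these days, with a median interaction of 0.29 (camera adjusted p = 8.18e-07, adjusted p = 0.00257 with an estimated correlation), 0 called over all genes and 1 adjusted over the list alone. The mitosis list had a median interaction of -1.23 from QSC to 1 DPI and 0.63 from 1 to 3 DPI, with adjusted p = 0.699 and 0.999 with an estimated correlation, 0 called over all genes, and 3 and 0 adjusted over the list alone; the QSC median in it was 0.65, and 0.05 without KO QSC library 3. Without libraries of low array weight limma called 2 genes between 1 and 3 DPI, and without KO QSC library 1 it called 12 between QSC and 1 DPI.

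Injury was compared with rest in control cells to describe activation. Spp1, a secreted phosphoprotein of injured tissue, rose to 1240 ± 740 TPM (SD, n = 4) at 1 DPI from 2.86 ± 3.44 TPM (n = 3), a log2 fold change of 8.45 (limma adjusted p = 5.55e-10). Mki67 rose from 0.497 ± 0.339 to 35.7 ± 11 TPM (log2 4.59, limma adjusted p = 2.61e-07). Pax7, the satellite cell transcription factor, rose from 6.61 ± 1.40 to 14.3 ± 4.59 TPM (0.96, adjusted p = 0.0309), a call lost in 8 of 15 alternative fits. Erfe, the hormone erythroferrone, fell from 567 ± 104 to 18.1 ± 4.80 TPM (log2 -4.91, adjusted p = 4.40e-08). Myod1 (-0.38) and Myog (-0.83) did not pass.

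All 29 mitosis genes and all 30 S phase genes were called higher at 1 DPI in control cells, with medians of 4.28 and 3.26 (camera adjusted p = 2.74e-23 and 1.57e-24, both adjusted p = 0.179 with an estimated correlation), and as many adjusted over the list alone. Of 78 mitochondrial ribosomal proteins 73 rose, 74 adjusted over the list alone (median 1.96, camera adjusted p = 5.27e-30, adjusted p = 0.179 with an estimated correlation). Of 76 OXPHOS subunits 70 rose, 70 adjusted over the list alone (median 1.13, camera adjusted p = 1.35e-24, adjusted p = 0.3 with an estimated correlation). Of 29 quiescence genes 11 fell and 2 rose, the same counts adjusted over the list alone (median -0.50, camera adjusted p = 0.000209, adjusted p = 0.333 with an estimated correlation), including the syndecan Sdc4 at -2.42 and the adhesion molecule Vcam1 at -1.64. Median-of-ratios scaling lowered the median of all genes by a shift of -0.20, and under it these medians were 3.96, 2.92, 1.60, 0.77 and -0.81, so no direction flipped. Markers of other cells moved with the same contrast. Of 20 macrophage and monocyte markers 18 rose, 20 adjusted over the list alone (median 3.24, camera adjusted p = 5.7e-05, adjusted p = 0.542 with an estimated correlation). Of 10 neutrophil markers 7 rose, 7 adjusted over the list alone (median 3.85, camera adjusted p = 0.0215, adjusted p = 0.55 with an estimated correlation), and S100a9, a neutrophil protein, went from 1.26 ± 1.68 to 792 ± 635 TPM. Under the scaling both marker medians stayed above 0, at 2.97 and 3.68.

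**Figure D3:**
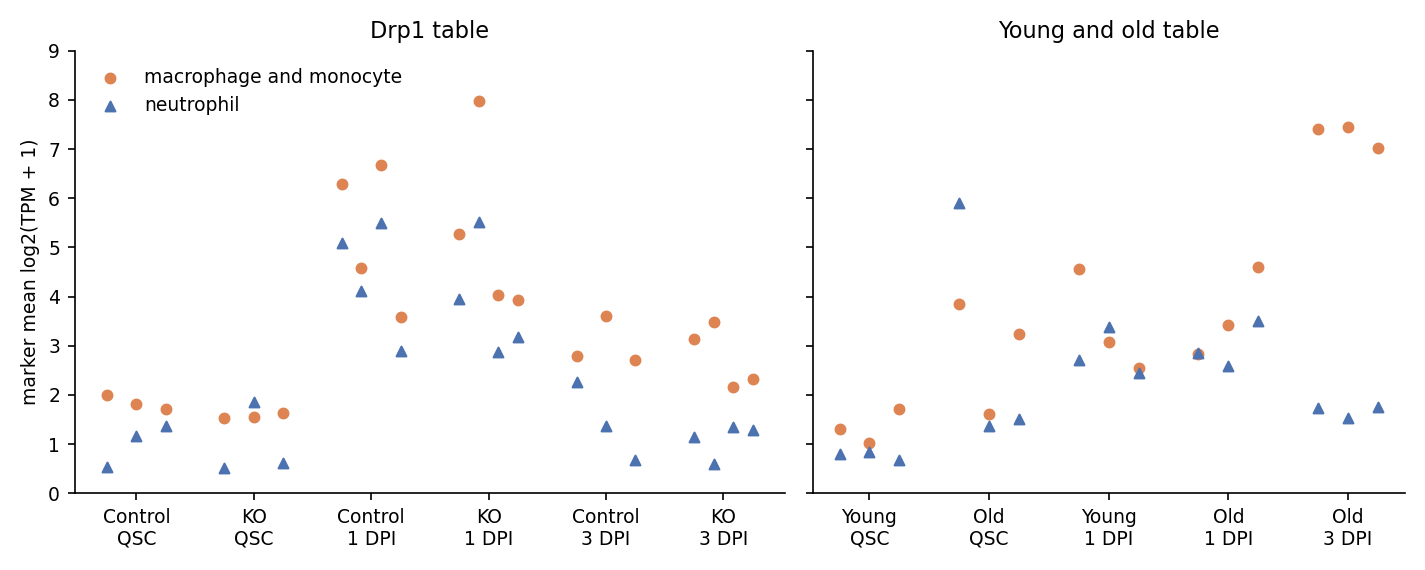
Mean log2(TPM + 1) of the macrophage and monocyte list and of the neutrophil list on the vertical axis, with 1 pair of points per library, by group in each table. Macrophage means lie between 3.59 and 7.98 in the 8 libraries of the Drp1 table at 1 DPI, and between 7.02 and 7.45 in the 3 old 3 DPI libraries.

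In control cells 6581 genes passed limma at 1 DPI against QSC, 4268 higher and 2313 lower, which is 64.9% higher. Under the scaling 6965 passed, 3273 higher and 3692 lower, or 47.0% higher, so the split between higher and lower genes rests on the scale. KO cells gave 5897 calls, 3959 higher and 1938 lower (67.1% higher), against 2961 higher and 3233 lower (47.8%) under the scaling, which shifted the median by -0.20. In KO cells Spp1 (9.15), Clec4e (7.53) and Il1b (7.03) rose at 1 DPI, all genes of inflammation (7.15, 3.68 and 3.65 with the marker covariate), and Mki67 rose by a log2 of 2.93. Myog fell from 91.2 ± 76.8 to 18.1 ± 9.32 TPM (log2 -1.88, limma adjusted p = 0.0145). The 3 KO QSC libraries stood at 15.98, 88.2 and 169.5 TPM, and the call was lost without library 2 (-1.63, adjusted p = 0.0713) or library 3 (-1.17, adjusted p = 0.131), with only these 2 groups fitted and with the replicate block. Pax7 (0.78) and Myod1 (-0.28) did not pass. S phase (30 of 30 called higher, median 3.26), mitosis (29 of 29, median 3.08) and mitochondrial ribosomal genes (73 of 78, median 1.54) rose in KO cells as well, with adjusted p of 0.14, 0.225 and 0.202 with an estimated correlation and the same counts adjusted over the list alone. Under the scaling these medians were 2.98, 2.77 and 1.21. In the same contrast 18 of 20 macrophage markers rose, 20 adjusted over the list alone (median 3.47, camera adjusted p = 2.39e-06, adjusted p = 0.476 with an estimated correlation, 3.22 under the scaling).

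From 1 to 3 DPI, control cells were compared to describe differentiation. The labels give another sort at 3 DPI, a CD34-YFP+ fraction, so day and gate cannot be separated in this step in control or KO cells. Myog, a driver of myogenic differentiation, rose from 17.9 ± 11 to 846 ± 126 TPM (log2 5.64, SE 0.56, limma adjusted p = 1.25e-06). Mymx, which encodes a peptide of myoblast fusion, rose to 75.1 ± 4.65 TPM from 0.260 ± 0.521 TPM (log2 5.99, limma adjusted p = 9.58e-08). Pax7 fell from 14.3 ± 4.59 to 6.24 ± 0.817 TPM (log2 -1.02, limma adjusted p = 0.0499), a call lost in 10 of 15 alternative fits. Among genes of blood-derived cells, S100a8 fell by 7.06, Hcar2 by 6.60 and Il1r2 by 6.22 on the log2 scale; with the marker means as a covariate these were 4.35, 4.09 and 3.54. Of 27 differentiation genes 22 rose, 22 adjusted over the list alone (median 3.16, camera adjusted p = 3.49e-34, adjusted p = 0.0015 with an estimated correlation). Of 76 OXPHOS subunits 65 rose, 70 adjusted over the list alone (median 0.70, camera adjusted p = 1.23e-50, adjusted p = 0.0381 with an estimated correlation). Of 21 immediate-early genes 18 fell, 18 adjusted over the list alone (median -1.54, adjusted p = 0.0124 with an estimated correlation), with Fosb at -2.66 and Egr1 at -2.74. Of 21 NF-kB and chemokine genes 18 fell, 20 adjusted over the list alone (median -3.21, adjusted p = 0.0184 with an estimated correlation). No direction of these 4 lists flipped under the scaling. Of 20 macrophage markers 6 fell beside them, 12 adjusted over the list alone (median -2.19, camera adjusted p = 1.61e-05, adjusted p = 0.338 with an estimated correlation).

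In control cells 2446 genes passed limma between 3 and 1 DPI, 933 higher and 1513 lower (38.1% higher), against 1204 higher and 1294 lower (48.2%) under the scaling. Without control 3 DPI library 2 the count was 1526, without library 3 it was 1584, and with the macrophage and neutrophil marker means as a covariate 1546. KO cells gave 3464 calls, 1247 higher and 2217 lower. In KO cells Mymk, a myoblast fusion protein, rose from 1.73 ± 1.21 to 125 ± 21.3 TPM (log2 5.68) and Myog to 782 ± 103 TPM (5.49). Mymx was at 67.9 ± 9.73 TPM and listed at 0 in all 4 KO libraries at 1 DPI. S100a8 fell by 6.29 on the log2 scale, Pax7 by 1.29 and Myod1 by 0.65; the call of Myod1 was lost in 9 of 16 alternative fits, and that of S100a8 with the marker covariate (-3.45, adjusted p = 0.0854) and with the replicate block. Of the differentiation list 22 genes rose and 1 fell in KO cells, as many adjusted over the list alone (median 3.09, adjusted p = 0.00346 with an estimated correlation), and 69 OXPHOS subunits rose, 70 adjusted over the list alone (median 0.75, adjusted p = 0.047 with an estimated correlation). The KO count was 1764 with only these 2 groups fitted, 1843 with the marker covariate and 2156 without libraries of low array weight.

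Old and young cells were compared at rest to ask what ageing changes in quiescence. Ccl11, the chemokine eotaxin, rose to 389 ± 41.4 TPM (SD, n = 3) in old cells from 16.8 ± 10.6 TPM (n = 3), a log2 fold change of 4.61 (SE 0.37, limma adjusted p = 0.000104). Rtn1, a reticulon of the endoplasmic reticulum, rose from 0.269 ± 0.402 to 7.42 ± 3.23 TPM (2.70, adjusted p = 0.00284), and Cd52, a surface peptide of leukocytes, from 3.34 ± 1.57 to 27.9 ± 15 TPM (2.62, adjusted p = 0.0407). Sox11, a transcription factor, fell from 18.6 ± 2.63 to 1.87 ± 0.743 TPM (log2 -2.80, adjusted p = 0.000198), Oxtr, the oxytocin receptor, from 11.3 ± 2.48 to 0.425 ± 0.524 TPM (-3.15, adjusted p = 0.000198), and Elk3 from 40.2 ± 5.56 to 8.86 ± 4.86 TPM (-2.21). Of 14 alternative fits the call was lost in 9 for Cd52, 7 for Elk3 and 2 or fewer for Ccl11, Rtn1, Sox11 and Oxtr. Cd52 stood at 1.68 with the marker covariate and at 1.49 with only old library 2 kept by array weight. Pax7 was at 6.80 ± 1.60 against 6.11 ± 0.425 TPM and Myod1 at 399 ± 192 against 648 ± 30.3 TPM (-0.80, limma adjusted p = 0.208). Myog (-0.55), Mki67 (-0.74), Cdkn1a (-0.01) and Dnm1l, at 27.3 ± 11.2 against 33.4 ± 3.74 TPM (-0.37, adjusted p = 0.601), did not pass.

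Matrix and TGF-beta genes lay below 0 in old QSC for 25 of 27 members, with 2 called and 11 adjusted over the list alone (median -0.86, camera adjusted p = 9.64e-09, adjusted p = 0.51 with an estimated correlation). Sparc, a matrix glycoprotein, fell from 673 ± 105 to 215 ± 61.7 TPM (log2 -1.67, limma adjusted p = 0.000716) and Col3a1, a fibrillar collagen, from 233 ± 50.8 to 39.4 ± 29.7 TPM (-2.75, adjusted p = 0.0106). Col3a1 lost its call with the marker covariate (-1.89, adjusted p = 0.237), without young QSC library 5 (0.0648) and with only these groups fitted. With 1 old library left by array weight, Col3a1 stood at -1.63. OXPHOS subunits lay below 0 for 66 of 76, with 1 called and 7 adjusted over the list alone (median -0.25, camera adjusted p = 9.64e-09, adjusted p = 0.565 with an estimated correlation), and Sdhd, a subunit of succinate dehydrogenase, fell from 115 ± 9.89 to 68.0 ± 8.32 TPM (-0.75). TCA cycle genes lay below 0 for 17 of 19, with 1 called and 8 adjusted over the list alone (median -0.40, camera adjusted p = 1.72e-06, adjusted p = 0.51 with an estimated correlation). Interferon genes lay above 0 for 25 of 29, with 2 called and 3 adjusted over the list alone (median 0.75, camera adjusted p = 4.43e-08, adjusted p = 0.565 with an estimated correlation), and Rtp4 rose from 5.31 ± 1.49 to 26.3 ± 6.08 TPM (2.11). Cytosolic ribosomal proteins lay below 0 for 70 of 75, with 0 called and 0 adjusted over the list alone (median -0.16, camera adjusted p = 1.09e-06, adjusted p = 0.565 with an estimated correlation). Mitosis genes lay below 0 for 26 of 29, with 0 called and 0 adjusted over the list alone (median -0.58, camera adjusted p = 0.00107, adjusted p = 0.565 with an estimated correlation). The calls of Sdhd and Rtp4 were each lost in 9 of 14 alternative fits. None of these directions flipped under the scaling, but cytosolic ribosomal proteins lost the call (-0.08, camera adjusted p = 0.0661), and mitosis did without young library 5 (-0.41, 0.0508).

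Markers of other cells also differed with age at rest. Those of fibro-adipogenic progenitors lay above 0 for 13 of 16, with 1 called and 1 adjusted over the list alone (median 0.50, camera adjusted p = 0.0122, adjusted p = 0.565 with an estimated correlation), and their means were 3.36 to 3.65 log2(TPM + 1) in old and 2.82 to 3.14 in young libraries. Macrophage markers lay above 0 for 19 of 20, with 1 called and 6 adjusted over the list alone (median 1.57, camera adjusted p = 4.01e-07, adjusted p = 0.565 with an estimated correlation), and Cd14, a macrophage receptor, rose from 15.1 ± 5.25 to 81.2 ± 22 TPM (2.36, limma adjusted p = 0.041), a call lost in 9 of 14 alternative fits. Neutrophil markers lay above 0 for 7 of 8, with 0 called and 0 adjusted over the list alone (median 2.52, camera adjusted p = 0.00466, adjusted p = 0.565 with an estimated correlation). Old QSC library 1 had a macrophage mean of 3.84 and a neutrophil mean of 5.90 log2(TPM + 1), old library 3 had 3.25 and 1.51, and old library 2 had 1.61 and 1.38. The young libraries had 1.03 to 1.7 and 0.67 to 0.84. With the marker means as a covariate the interferon median was 0.36 (camera adjusted p = 0.0754). Without the libraries of low array weight, only library 2 of old QSC was left, and the medians were 0.21 for macrophage markers and -0.08 for OXPHOS.

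At rest 123 of 16949 genes passed limma between ages, 58 higher and 65 lower in old cells (47.2% higher), and 156 under the scaling, 100 higher and 56 lower (64.1%). The count moved with single libraries: it was 54, 15 and 22 without young QSC library 4, 5 or 6, and 44 and 293 without old QSC library 1 or 2. It was 1 with only the QSC groups fitted, 13 with the marker covariate, and 1582 among the same genes when all genes entered the fit.

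At 1 DPI, old cells were compared with young cells to ask whether ageing changes activation. Plk1, the kinase that drives mitotic entry, fell to 2.84 ± 1.59 TPM (SD, n = 3) in old cells from 27.4 ± 9.37 TPM (n = 3), a log2 fold change of -2.94 (SE 0.42, limma adjusted p = 0.0111). Cenpa fell from 52.5 ± 19.9 to 6.83 ± 3.09 TPM (-2.79, adjusted p = 0.0264), Aurka, a spindle kinase, from 44.9 ± 13.0 to 10.9 ± 3.24 TPM (-1.95, adjusted p = 0.0437), and Cdca3 from 38.4 ± 7.84 to 8.67 ± 5.07 TPM (-2.16, adjusted p = 0.0264). Ccnb1 (-2.75), which shares sequence with other genes, and Pimreg (-2.50) also fell. Of 14 alternative fits the call was lost in 12 for Ccnb1, 11 each for Aurka, Cdca3 and Pimreg, 9 for Cenpa and 5 for Plk1. Sox11 fell from 37.9 ± 3.71 to 3.65 ± 1.14 TPM (log2 -3.09, limma adjusted p = 0.00017). Serpina3m, a protease inhibitor, rose from 1.51 ± 1.26 to 24.2 ± 10.5 TPM (3.38, adjusted p = 0.00789), and Anxa3, an annexin, from 38.1 ± 3.98 to 118 ± 20.2 TPM (1.60, adjusted p = 0.00789). Gpnmb, a glycoprotein of phagocytes (2.09), also rose; its call was lost in 6 of the 14 fits, and that of Serpina3m in 4. Mki67 was at 6.65 ± 3.52 against 24.2 ± 5.98 TPM (-1.82, adjusted p = 0.121) and Myog at 9.36 ± 4.33 against 26.8 ± 6.55 TPM (-1.49, adjusted p = 0.145). Pax7 (-0.39), Myod1 (-0.16), Cdkn1a (-0.33) and Dnm1l (0.21, adjusted p = 0.954) did not pass.

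Mitosis genes lay below 0 in old cells at 1 DPI for 29 of 29 members, with 4 called over all genes and 29 adjusted over the list alone. Their median was -1.87 (limma camera adjusted p = 2.04e-50, and adjusted p = 0.0215 with an estimated correlation). The list means were 3.56, 2.78 and 4.20 log2(TPM + 1) in the old libraries and 5.56, 5.18 and 5.73 in the young ones. S phase genes lay below 0 for 26 of 30, with 0 called and 0 adjusted over the list alone (median -0.26, camera adjusted p = 0.000733, adjusted p = 0.532 with an estimated correlation), and without old library 2 the median was -0.07 (camera adjusted p = 0.321). With an estimated correlation the mitosis adjusted p was 0.511 with only the 1 DPI groups fitted, 0.153 without libraries of low array weight, and 0.0583 to 0.0709 without young library 5, young library 7 or old library 1; the median stayed between -2.20 and -1.57.

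**Figure D4:**
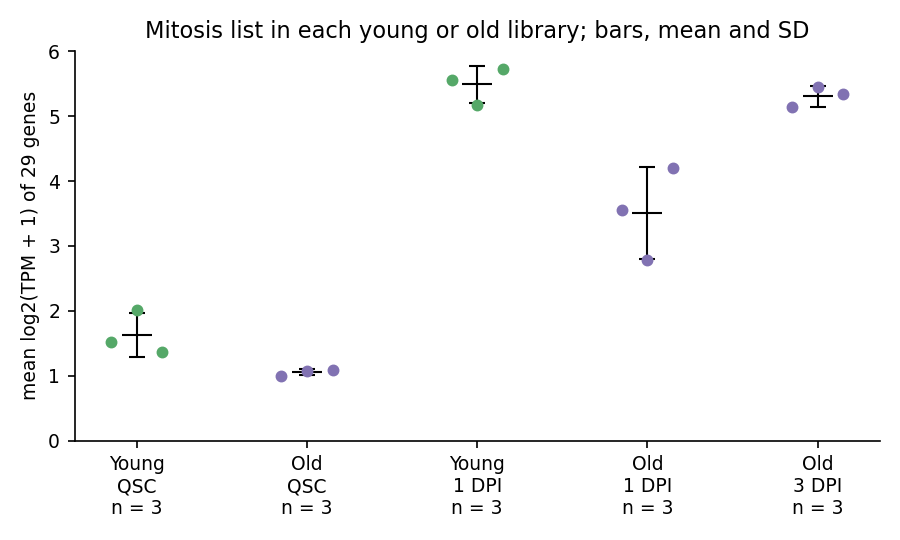
Mean log2(TPM + 1) of the 29 mitosis genes on the vertical axis, with 1 point per library of the young and old table; lines and bars are the mean and SD of each group. At 1 DPI the old libraries lie at 2.78 to 4.20 and the young ones at 5.18 to 5.73, a direction that median-of-ratios scaling did not flip.

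Matrix and TGF-beta genes again lay below 0 in old cells at 1 DPI for 23 of 27, with 1 called and 9 adjusted over the list alone (median -0.66, camera adjusted p = 2.57e-09, adjusted p = 0.242 with an estimated correlation), and Col1a2, a fibrillar collagen, fell from 9.17 ± 2.70 to 2.48 ± 0.643 TPM (-1.53), a call lost in 11 of 14 alternative fits. The matrix median was -0.26 without old library 3. Markers of tenocytes (median -0.78) and of fibro-adipogenic progenitors (-0.58) moved with it (camera adjusted p = 0.00898 and 0.00242, adjusted p = 0.242 and 0.353 with an estimated correlation), with 0 called, 2 and 1 adjusted over the list alone, and both calls lost without old library 2 (0.0777 and 0.123). Differentiation genes lay below 0 for 21 of 27, with 0 called and 3 adjusted over the list alone (median -0.57, camera adjusted p = 3.9e-06, adjusted p = 0.353 with an estimated correlation). Interferon genes lay above 0 for 20 of 29, with 0 called and 0 adjusted over the list alone (median 0.47, camera adjusted p = 3.9e-06, adjusted p = 0.457 with an estimated correlation), and without old 1 DPI library 3 the median was 0.23 (camera adjusted p = 0.0799), and without library 2 0.82. Markers of mature myofibres lay below 0 for 15 of 18, with 0 called and 4 adjusted over the list alone (median -0.93, camera adjusted p = 3.62e-07, adjusted p = 0.242 with an estimated correlation). These directions did not flip under the scaling.

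At 1 DPI 24 genes passed limma between ages, 12 higher and 12 lower, against 11 higher and 4 lower under the scaling (50% and 73.3% higher). The count was 9 without young library 7, 12 without old library 1, 4 without old library 2, and 36 without old library 3. It was 7 with a pseudocount of 0.1, 5 with none, 9 with only these groups fitted and 159 with array weights.

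The change of the age difference from QSC to 1 DPI was tested as an interaction, which called 2 of 16949 genes. Oxtr had an interaction of 3.15 (SE 0.40, limma adjusted p = 0.0191): at 1 DPI it lay at or near its lowest value in the table, which stands for 0, in both ages. Gm48294, a predicted model named after its values were seen, had -3.27 (adjusted p = 0.0191). Both calls were lost in 10 of 19 alternative fits. The mitosis list had a median interaction of -1.39 (camera adjusted p = 2.08e-17, adjusted p = 0.25 with an estimated correlation), with 0 called over all genes and 11 adjusted over the list alone. The number of genes was 0 with a pseudocount of 0.1, with none or with the marker covariate, and 7 with no filter.

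Young and old cells were each compared between QSC and 1 DPI. In young cells Spp1 rose from 3.13 ± 2.04 to 747 ± 130 TPM (log2 7.60) and the chemokine Ccl6 by 6.66 on the log2 scale, while Erfe fell by 4.85. Pax7 rose from 6.11 ± 0.425 to 26.4 ± 5.85 TPM (1.93, limma adjusted p = 0.000137), Mki67 rose by 3.41, and Myod1 fell from 648 ± 30.3 to 365 ± 68.3 TPM (-0.84, adjusted p = 0.0327). The call of Myod1 was lost in 7 of 15 alternative fits: with the marker covariate (-0.03, adjusted p = 0.96), with no filter, without any 1 of the young QSC libraries and without young 1 DPI library 5 or 6. In old cells Pf4, platelet factor 4, rose to 98.1 ± 74.0 TPM from its lowest value in the table, which stands for 0 there, and Pax7 rose from 6.80 ± 1.60 to 20.01 ± 4.92 TPM (1.42, adjusted p = 0.00137) and Mki67 by 2.33. Mitochondrial ribosomal genes rose for 67 of 78 in young cells, where 1 fell, and for 73 of 78 in old cells (medians 1.59 and 1.93, adjusted p = 0.131 and 0.0835 with an estimated correlation), as many adjusted over the list alone. Mitosis genes rose for 29 and 26 of 29 (medians 3.6 and 2.66, adjusted p = 0.173 and 0.249 with an estimated correlation), as many adjusted over the list alone. Under the scaling, which shifted the median of all genes by -0.25 in young and -0.31 in old cells, these medians were 1.21, 1.49, 3.26 and 2.34. Macrophage means were 1.03 to 1.7 log2(TPM + 1) in young QSC and 2.54 to 4.56 at 1 DPI, where 8 of 20 markers rose, 10 adjusted over the list alone (median 1.87, camera adjusted p = 0.0176, adjusted p = 0.756 with an estimated correlation), and neutrophil means 0.67 to 0.84 and 2.45 to 3.38. In old cells the macrophage markers did not pass (0.71, camera adjusted p = 0.882).

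Young cells gave 5424 calls, 3934 higher and 1490 lower (72.5% higher), against 2692 higher and 2519 lower (51.7%) under the scaling. Old cells gave 5511 calls, 4202 higher and 1309 lower (76.2%), against 2884 higher and 2545 lower (53.1%). With the marker covariate 3300 genes passed in young cells.

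Old cells were followed to 3 DPI, without young cells of that day in the same table, so age was not compared there. Chrng, the embryonic subunit of the acetylcholine receptor, rose to 253 ± 98.9 TPM (SD, n = 3) from its lowest value in the table (n = 3), which stands for 0 (limma adjusted p = 1.22e-07), and Myog rose from 9.36 ± 4.33 to 511 ± 160 TPM (5.67). Pax7 fell from 20.01 ± 4.92 to 4.67 ± 1.36 TPM (-1.89, adjusted p = 0.000569), Myod1 fell from 331 ± 77.7 to 70.8 ± 15.5 TPM (-2.20, adjusted p = 0.000175), and Mki67 rose from 6.65 ± 3.52 to 18.3 ± 1.39 TPM (1.46), the last a call lost in 8 of 15 alternative fits. Of 27 differentiation genes 22 rose, 22 adjusted over the list alone (median 3.70, camera adjusted p = 2.03e-29, adjusted p = 0.00997 with an estimated correlation). Markers of other cells rose beside them: 16 of 20 macrophage markers, 18 adjusted over the list alone (median 3.77, camera adjusted p = 1.27e-17, adjusted p = 0.065 with an estimated correlation), and 7 of 10 glial and Schwann markers with 1 lower, as many adjusted over the list alone (median 1.91, camera adjusted p = 3.54e-06, adjusted p = 0.00997 with an estimated correlation). H2-Aa, an MHC class II chain, rose from 2.46 ± 3.96 to 270 ± 94.5 TPM (6.86). With the marker covariate the calls of Pax7 and H2-Aa were lost. The macrophage means were 7.02 to 7.45 log2(TPM + 1) at 3 DPI and 2.83 to 4.59 at 1 DPI. No direction of these 3 lists flipped under the scaling, which shifted the median of all genes by 0.22. Of 16949 genes 2974 passed, 973 higher and 2001 lower (32.7% higher), against 1320 and 1059 under the scaling (55.5%). The count was 1906 without old 1 DPI library 1, 1845 without library 2, 1808 with only these groups fitted, and 807 with the marker covariate.

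The tables were set side by side to ask whether Drp1 loss and ageing moved the same genes. Across 16378 genes, which are not independent replicates, the KO and age fold changes had a Pearson correlation of -0.0649 in QSC (Spearman -0.121) and 0.0392 at 1 DPI (Spearman 0.0535). No gene was called by limma in both, of 18 and 121 called in QSC and of 24 and 21 at 1 DPI, where unrelated lists would share 0.0665 and 0.0167 with the same sign. The 100 genes most raised in KO QSC had a median age difference of -0.29 (camera adjusted p = 0.00441, adjusted p = 0.0954 with an estimated correlation), and the 100 most lowered had 0.10 (camera adjusted p = 0.00441, adjusted p = 0.0954 with an estimated correlation). At 1 DPI the corresponding sets did not pass (adjusted p = 0.341 and 0.154). For the injury response of control cells and of young cells the correlation across genes was 0.734 (Spearman 0.73). Of 6417 and 5401 genes called at 1 DPI against QSC, 3977 were called in both with the same sign, where unrelated lists would share 1210, and 19 with opposite signs, where 909 would.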

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

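Tests chosen only after the result was seen were those of shared reads, sequence variants, blood-derived RNA, detected genes, dilution and general loss; those of the chromosome 16 segment, the factor per gene and the splits were set before. Gene lists and genes below were taken because a library lay far from the other 3 of its group or because an interaction passed its test.

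Most genes called between KO and control cells were pseudogenes and predicted models, 59 of the 85 called in any state. A chromosomal segment carried with the Dnm1l allele would put most of them on chromosome 16, which held 4.7% of the 85 (95% exact interval 1.3 to 11.6%), against 3.1% of tested genes, so the tables argue against it as the main source. Reads shared with near-identical copies stay open: 66.7% of 30 pseudogene and parent pairs had opposite signs (interval 47.2 to 82.7%). With 1 pair per parent it was 12 of 20 (36.1 to 80.9%). Pairs with Eno1b, a copy of Eno1, counted as same sign, and only 2 parents were called. Sequence variants against the reference may contribute, as 78.0% of the 59 kept their sign in all states (65.3 to 87.7%), though strain labels match. A constant genotype effect, untested, would also keep the sign and stays open.

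Macrophage and neutrophil markers differed widely between replicate libraries at 1 DPI, with macrophage means of 3.59 to 7.98 log2(TPM + 1) over the 8 libraries, against 1.52 to 2.0 in QSC, and S100a8, an abundant neutrophil gene, at 1396 ± 1120 TPM in control cells. The lists, which share no gene, rose and fell together across these libraries (Pearson r = 0.95, exact permutation p = 0.000347, adjusted 0.000694; Spearman 0.905, exact permutation p = 0.00456; r = 0.946 without KO library 2 and control library 3). RNA of blood-derived cells in the sorted fraction is therefore a candidate source, although a sort for YFP should remove such cells. Fewer detected genes in those libraries would need r below -0.5 with the macrophage mean, but r was 0.65 (exact permutation p = 0.0814, adjusted 0.0814; Spearman 0.5, exact permutation p = 0.216; 0.758 without those libraries), on the other side of 0 without passing, so nothing supports it. No biological explanation was tested, and the injury itself draws such cells into muscle.

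Mitosis genes were lower in old than in young cells at 1 DPI, with a median of -1.87. Dilution by other RNA would lower the myogenic activation list as much, but its median was -0.088 (95% bootstrap interval -0.22 to 0.113), which argues against dilution as the whole source. A general loss of genes of that level would place the list within random lists of like expression, whose medians ran from -0.18 to 0.17 over their central 95%, with the lowest at -0.377. The factor per gene cancels without a pseudocount, where the median was -2.01 (bootstrap error 0.126). Age, which the design names, stays open as an untested hypothesis, as does any other difference between the mice.

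In groups of 4 libraries, 16 of 177 items had a library far from the other 3. Items share libraries, so no chance rate applies. KO 1 DPI library 2 held 6. Its list means were 7.94 for OXPHOS (others 8.38 to 8.46), 9.58 for cytosolic ribosomal proteins (others 10.2) and 4.56 for interferon genes (others 2.89 to 3.04), all in log2(TPM + 1). The 50 highest genes took 27.8% of its TPM (others 22.2 to 22.9%), mitochondrial mRNAs 12.7% (others 5.32 to 6.43%), and Atp5g3 stood at 423 TPM (others 537 to 556).

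KO 3 DPI library 3 had Eno1b at 226 TPM (others 953 to 1020) and Cxcl3 at 1.94 TPM (others 0). Fgf21 was at 38.4 TPM in KO 3 DPI library 2 (others 24.1 to 26.0), and Rps7 at 580 TPM in KO 1 DPI library 1 (others 846 to 864). Control 1 DPI library 4 had Mir1b at 116 and Mymx at 1.04 TPM (others 0, so any value is far). Control 1 DPI library 3 had a heat shock mean of 7.97 (others 8.15 to 8.17) and a pericyte and smooth muscle marker mean of 3.44 (others 2.71 to 2.82). The integrated stress response mean was 5.29 in control 1 DPI library 1 (others 5.12 to 5.13). The fibro-adipogenic progenitor marker mean was 2.26 in KO 3 DPI library 1 (others 1.57 to 1.67).

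Genes whose genotype difference changed from QSC to 1 DPI by limma were Gm24682 (interaction -4.27, adjusted p = 4.01e-06), Gm5874 (-3.85, adjusted p = 0.000244), Gm14893 (1.86, adjusted p = 0.00513) and Gm2427 (-2.76, adjusted p = 0.0311). Genes whose age difference changed were Oxtr (3.15) and Gm48294 (-3.27), both at adjusted p = 0.0191.

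Gene lists whose genotype difference changed from QSC to 1 DPI, by camera with a preset correlation, had median interactions of -0.33 for OXPHOS, -0.22 for mitochondrial ribosomal proteins, -0.29 for the TCA cycle, -1.23 for mitosis (whose QSC median rests on KO QSC library 3), 0.29 for immediate-early genes, 0.35 for interferon genes and 0.47 for mature myofibre markers. Their adjusted p were 0.699 to 0.785 with an estimated correlation. From 1 to 3 DPI the medians were 0.29 for the integrated stress response (adjusted p = 0.00257 with an estimated correlation), 0.17 for S phase, 0.63 for mitosis and -0.45 for interferon genes (each 0.999).

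Gene lists whose age difference changed from QSC to 1 DPI by the preset test had adjusted p of 0.25 to 0.649 with an estimated correlation. Median interactions above 0 were 0.16 for OXPHOS, 0.33 for mitochondrial ribosomal proteins, 0.25 for cytosolic ribosomal proteins, 0.28 for the TCA cycle, 0.36 for the integrated stress response, 0.34 for the mitochondrial unfolded protein response and 0.88 for cholesterol synthesis. Those below 0 were -1.39 for mitosis, -0.37 for differentiation, -0.38 for immediate-early genes and -0.64 for NF-kB and chemokine genes. Marker lists had -1.42 for macrophages, -1.60 for neutrophils, -1.01 for fibro-adipogenic progenitors, -1.20 for tenocytes and -0.63 for mature myofibres.

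Other splits of the same libraries were fitted to ask whether chance gives as many calls. Unadjusted over comparisons, only the real one of 35 splits gave as many for KO against control at 3 DPI (52, highest other 26). So it was for 1 DPI against QSC in control (6581, other 3773) and KO cells (5897, other 3477). So it was for 3 against 1 DPI (2446, other 1127, and 3464, other 29). Between genotypes at 1 DPI 4 of 35 splits gave at least the 51 real calls. But 35 of the 51 recurred at 3 DPI with the same sign (0.0715 expected), which argues against chance for those alone. The highest other, 765, joined control libraries 1 and 3 with KO libraries 1 and 2, of highest macrophage means in their groups. That split points to a structure other than genotype. Chance also stays open for 2 interactions. For genotype from QSC to 1 DPI 33 of 100 drawn splits gave at least the 4 real calls (highest 36). For age 66 of 100 gave at least the 2 (highest 24). These 2 highest splits also point to a structure of the samples. From 1 to 3 DPI the real count was 0, which any split reaches, so that test is void.

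For comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real and highest other counts were 39 and 12 for KO QSC, 123 and 5 for old QSC, 24 and 5 for old 1 DPI, 5424 and 5 for young injury, 5511 and 3 for old injury, and 2974 and 3 for old 3 against 1 DPI. The correlations of the KO effect with the age effect also had 10 splits, of which 2 in QSC and 3 at 1 DPI were as large, with highest others of 0.0667 and 0.0695, and the injury correlation had a highest other of 0.556.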

How the results depend on the processing

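Chosen after seeing the data were the marker covariate, dropping libraries of low array weight, no pseudocount, genes for scaling in the young and old table and lists under every setting. The others were planned. No called result of a named gene reversed, which the choice of called genes without overlap largely ensured. Genes called in both fits, selected likewise, all kept their sign, except under the marker covariate. There 3969 of 3975 for control and 3418 of 3421 for KO 1 DPI against QSC did. The majority of calls turned between higher and lower under the scaling for control and KO 1 DPI against QSC, old QSC and old 3 against 1 DPI, with counts in the report, and under other settings for the 3 genotype comparisons, old QSC and the genotype interaction from QSC to 1 DPI. Medians of lists past the preset test that turned without a single library are given in the report, except NF-kB and chemokine genes in old QSC, at 0.17 and at -0.08 without young library 5 or -0.06 without old library 2. Cytosolic ribosomal proteins at KO 1 DPI turned to 0.04 without libraries of low array weight, and macrophage markers in old QSC to -0.13 with the covariate made from them. With no filter 6 lists in old QSC changed side in camera with medians still below 0. Of 121 called results of named genes, 89 lost the call under at least 1 setting; where a count moved, the cause was not tested, except that fewer libraries were fitted in leave-one-out. Depth is unknown, so its limit cannot be given.

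Only the groups compared gave 23 calls for KO QSC, 33 for KO 1 DPI, 1764 for KO 3 against 1 DPI, 1 for old QSC, 9 for old 1 DPI and 1808 for old 3 against 1 DPI; Dnm1l at 3 DPI stayed at -1.21 (adjusted p = 0.131). No filter gave 81 for KO QSC, 17 for the genotype interaction from QSC to 1 DPI, 7 for the age interaction, and 26431, 31042 and 29302 for old QSC, old 1 DPI against QSC and old 3 against 1 DPI. In those 3, genes with all libraries at a shared value enter the fit, and 1582 of the old QSC calls lay among the genes of the filtered fit. Array weights gave 75 for KO QSC and 159 for old 1 DPI, and scaling 15 for old 1 DPI. A pseudocount of 0.1 gave 7 for old 1 DPI and 0 for the age interaction, and no pseudocount 5 and 0.

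The marker covariate gave 1546 for control 3 against 1 DPI, 1843 for KO 3 against 1 DPI, 13 for old QSC, 0 for the age interaction, 3300 for young 1 DPI against QSC, 807 for old 3 against 1 DPI, and an injury correlation of 0.622. Without libraries of low array weight there were 2 and 2 calls for the genotype interactions, 2156 for KO 3 against 1 DPI, 21 for old QSC and 8 for the age interaction. Of 46 lists past the preset test between genotypes and ages, 2 passed with an estimated correlation.

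Replicate number as a block gave 3, 14 and 0 calls for KO QSC, 1 DPI and 3 DPI, 2 for the genotype interaction from QSC to 1 DPI, 0 for control 3 against 1 DPI, 1005 and 530 for KO 1 DPI against QSC and 3 against 1 DPI, 1679 for young 1 DPI against QSC and 606 for old 3 against 1 DPI; Dnm1l at 3 DPI was -1.15 (adjusted p = 0.792). Pairing is open: libraries of a number correlated at -0.212 to 0.192 around group means, all above 0.1 in no comparison. All 3 matched their own number best in control and old 1 DPI against QSC. The block was not run between ages, which share no numbers, or for the age interaction.

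Leave-one-out ranges were 32 to 60 for KO QSC (60 without KO library 1), 39 to 54 for KO 1 DPI, 42 to 61 for KO 3 DPI, 3 to 12 and 0 to 2 for the genotype interactions (12 without KO QSC library 1), 5566 to 6285 for control 1 DPI against QSC, 1526 to 2404 for control 3 against 1 DPI (1526 and 1584 without control 3 DPI library 2 or 3), 4689 to 5740 and 2907 to 3325 for the KO steps, 15 to 293 for old QSC, 4 to 36 for old 1 DPI, 0 to 8 for the age interaction, 4347 to 4656 for young 1 DPI against QSC, and 4603 to 5192 and 1845 to 2824 for the old steps. Dnm1l ran from -0.11 to 0.09 in QSC, -0.57 to -0.41 at 1 DPI and -1.35 to -1.11 at 3 DPI.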

Other observations

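No test in this part was chosen after its result was seen, but the genes and lists named were picked after their values were known, from those fixed beforehand except Gm49521. Fission and fusion genes, the machinery of Drp1, were examined in activation. In control cells 12 of 25 were called higher and 2 lower at 1 DPI against QSC, 14 and 3 adjusted over the list alone (median 0.86, camera adjusted p = 0.0087, adjusted p = 0.388 with an estimated correlation). Opa1, which fuses inner membranes, stood at 1.64, Mff, a Drp1 receptor, at 1.11, and Fis1 at 0.74, all past limma. The formin Inf2 stood at -2.05 and the ubiquitin ligase Mul1 at -0.87, also past limma. Dnm1l stood at 0.42 (limma adjusted p = 0.0725) in control, 0.55 (0.147) in young and 1.13 (0.00522) in old cells. Its old QSC value was 14.6 TPM in library 1 (others 31.7 and 35.5), and its age interaction was not called. In young cells 12 of the 25 rose and 1 fell, as many adjusted over the list alone (median 0.84, camera adjusted p = 0.00821, adjusted p = 0.364 with an estimated correlation). In old cells 15 of the 25 rose and 2 fell, 16 and 2 adjusted over the list alone (median 1.24, camera adjusted p = 0.000866, adjusted p = 0.249 with an estimated correlation). Under median-of-ratios scaling the list medians were 0.62 in control, 0.46 in young and 0.80 in old cells.

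The mRNAs encoded by mitochondrial DNA went the other way from nuclear-encoded OXPHOS subunits at 1 DPI in the young and old table. Of 13 such mRNAs, 11 fell in young cells (median -0.53, camera adjusted p = 3.34e-09, adjusted p = 0.247 with an estimated correlation) and 11 in old cells (median -0.71, camera adjusted p = 1.43e-10, adjusted p = 0.212 with an estimated correlation), as many adjusted over the list alone. From 1 to 3 DPI 12 of 13 rose in old cells, 12 adjusted over the list alone (median 0.78, camera adjusted p = 1.27e-17, adjusted p = 0.065 with an estimated correlation), with mt-Co1 at 1.21 and mt-Cytb at 0.78. Macrophage means stood at 2.83 to 4.59 log2(TPM + 1) at 1 DPI and 7.02 to 7.45 at 3 DPI in the same libraries. In the Drp1 table the 3 libraries of highest macrophage mean at 1 DPI (6.29 to 7.98), control 1 and 3 and KO 2, had mitochondrial mRNA means of 11.6 to 12.32, against 10.82 to 11.14 in the other 5. Control cells at 1 DPI against QSC had a median of -0.33 (camera adjusted p = 0.0614, adjusted p = 0.795 with an estimated correlation). Control cells from 1 to 3 DPI had a median of -0.42 for the same list. No direction flipped under the scaling, where the medians were -0.92, -1.16, 1.07, -0.69 and -0.34. Cholesterol synthesis genes rose for 19 of 24 in old cells at 1 DPI against QSC, 21 adjusted over the list alone (median 1.7, camera adjusted p = 2.96e-06, adjusted p = 0.274 with an estimated correlation), and fell for 16 of 24 from 1 to 3 DPI, 19 adjusted over the list alone (median -1.21, camera adjusted p = 1.17e-06, adjusted p = 0.251 with an estimated correlation), and neither direction flipped under the scaling. At 1 DPI 14 of 24 also rose in young cells, 15 adjusted over the list alone (median 1.07, adjusted p = 0.682 with an estimated correlation), and 14 in control cells, 14 adjusted over the list alone (0.81, adjusted p = 0.332 with an estimated correlation).

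Gm49521, a transcript on the opposite strand that overlaps Dnm1l and was picked for that position, stood at -1.16, -1.31 and -2.40 in KO cells in QSC, at 1 DPI and at 3 DPI (limma adjusted p = 0.530, 0.166 and 0.000997). It shares 196 bases with the Dnm1l transcript. Eno1, the parent of Eno1b, stood at -0.27, -0.50 (limma adjusted p = 0.0223 at 1 DPI) and -0.35 in the same comparisons, where Eno1b was higher.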
